A study of Mus musculus with 41 samples.

How the data were processed

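Fecal samples of mice were profiled by shotgun metagenomic sequencing. The table used holds 41 samples: 13 SPF, 13 LDP and 15 GMT samples in 16 groups: SPF or LDP by age, and GMT by transfer window. Sample titles spell LPD where the column names and design text have LDP, and both were read as low-dose penicillin. Library names of the 12 to 20 wk GMT samples read 13 wk, and the titles were followed. At 2 wk the library numbers are 2 and 3 where the titles give replicates 1 and 2, and the titles were followed. Per the labels, genomic DNA was sheared for libraries. Per the submitters' processing notes, fastp 0.23.1, Bowtie2 2.5.4 and the mouse genome GRCm39 (mm39) were used, without a stated role or order. The classifier, its database and the smallest abundance listed are not given in the sources used here. The deposited values are fractions of each sample assigned to a species by the authors, per the file headers, and each sample's species sum to 1. Sequencing depth is therefore unknown, no counts were inferred, and no interval that needs a depth is given. The smallest value above 0 lay between 7.73e-05% and 0.000455% in each sample, which bounds the precision of scarce taxa. The entries include 181 genera of viruses; viruses held at most 0.0521% and fungi at most 0.348% of a sample.

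Species were summed to the genus that the table gives for each. The table carries no ranks above genus, so a comparison at family rank was not run. Phyla were assigned by hand to 118 genera, which cover 88.8% of a sample on average. Genera and species entered a test when their mean fraction over the samples of the fit was at least 1e-04 (0.01%), and were taken as log2 of the fraction plus a pseudocount of 1e-05. limma 3.58.1 was fitted in R 4.3.3 with a mean per group, empirical Bayes moderation with an intensity trend, and contrasts that weight ages equally. SPF and LDP samples were fitted together (327 genera, 365 species), GMT samples separately (501 genera), and all samples jointly for GMT against SPF or LDP (397 genera). All tests are two-sided. p-values were adjusted by Benjamini-Hochberg per comparison, with a threshold of 0.05. Where a group has 2 samples, the spread is pooled over all groups of the fit.

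Sums over 16 lists of genera and over 9 phyla were compared by 100000 permutations of SPF and LDP samples within age, as was the Shannon index of species. The lists are Muribaculaceae, other Bacteroidales, Lactobacillaceae, Erysipelotrichales, segmented filamentous bacteria, Lachnospiraceae, Oscillospiraceae and relatives, butyrate producers, Enterobacterales, suckling-age cocci and Pasteurellaceae, mucus genera, sulfate reducers, Bifidobacteriaceae, Eggerthellales and Coriobacteriales, bacteria without a peptidoglycan wall, and reagent or soil genera. Community distance was Bray-Curtis on genus fractions. The share of distance variance was tested with adonis2 of vegan 2.7.1 and 9999 permutations within age. Each GMT sample's mean distance to SPF and to LDP samples of 8 to 12 wk was compared between windows by exact permutation. Other computing used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

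Taxa are named by a rule set before the data were examined, as were the comparisons and lists. Among taxa past the threshold with a mean of at least 0.1% in a group compared, the 12 largest log2 changes each way are named for LDP against SPF genera, 5 each way for other genus comparisons and 6 each way for species. Where fewer than 3 pass, the 3 with the smallest p are named as not passing. List genera and phyla of at least 0.1% and these named taxa are also followed in other comparisons.

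The fits were tested on simulated data in which 100 genera changed 2-fold and 100 changed 4-fold. For LDP against SPF at 4 to 12 wk, 91% of 2-fold and 99% of 4-fold changes were recovered, and 3 of 127 unchanged genera were called. After the simulated samples were rescaled to a total of 1, as fractions are, 54% of 2-fold and 100% of 4-fold changes were recovered, and 122 of 127 unchanged genera were called with a median log2 of -0.82. With a centred log-ratio of the rescaled samples these were 92%, 99% and 4. In comparisons of 2 samples per group, 60% to 72% of 2-fold and 90% to 93% of 4-fold changes were recovered, and 37% to 54% and 84% to 93% after rescaling.

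Alternatives tried were pseudocounts of 1e-06 and 1e-04, a filter of 1e-05 or none, a centred log-ratio, fractions of the bacterial total, moderation without trend, fits of only the groups compared, other age ranges, a per-genus permutation (10000 permutations), replicate numbers as a fixed or random block, and leaving out each sample in turn. Leaving out a sample of a pair assumes that the remaining sample varies like the other groups. Samples with the same number were checked for pairing before the fits were compared. Of 13 same-numbered LDP and SPF pairs of an age, 2 had residual correlations over 0.1, as had 29 of 60 same-numbered SPF or LDP pairs over ages and 8 of 21 pairs of GMT windows. Among other-numbered pairs 6 of 16, 25 of 80 and 27 of 63 had such correlations. In groups of 2 samples the residuals mirror each other, so correlations repeat, and other-numbered pairs carry the same value with the opposite sign. The LDP and SPF pairs of 2 wk, for example, had 0.151 when same-numbered and -0.151 otherwise. Between such groups these counts are not independent and cannot decide a pairing. The numbers were not taken as pairs in the main fits. Same-numbered samples of the 12 to 15 and 12 to 20 wk windows had correlations of 0.554, 0.359 and 0.125. A pairing of samples between these windows, or over ages, is therefore not excluded. SPF donor samples of 15 and 20 wk are not analysed here.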

Results

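The data are shotgun metagenomes of mouse feces, in which all DNA of a sample is sequenced and assigned to microbial species. Each of 41 samples was listed as relative abundances of species, in 2452 genera, and all levels are given here as percent of the listed total ± SD. Sample titles abbreviate the penicillin group LPD, read here as the LDP of the design text. Specific pathogen-free (SPF) mice and mice on low-dose penicillin (LDP) were sampled at 2, 4, 6, 8, 10 and 12 wk of age, with 2 samples per age and 3 at 8 wk. Penicillin is a beta-lactam antibiotic that blocks the building of the bacterial cell wall. A further 15 samples carry gut microbiota transfer (GMT) names with windows of 3 to 15 wk (n = 4), 8 to 15 wk (n = 4), 12 to 15 wk (n = 4) and 12 to 20 wk (n = 3). Library names of the last window read 13 wk; its samples were grouped by their titles. The design text names SPF donors of 15 and 20 wk, whose samples are not analysed here; which donors served which window, and the recipients, are not given in the sources used here. The sources do not state whether samples came from separate animals or cages, so p-values measure only the spread between these samples. Sequencing depth is unknown because the values are fractions. The 4 samples of 2 wk listed 2332 to 3502 species, the SPF and LDP samples of 4 wk and older listed 7564 to 9464, and the GMT samples 8039 to 9243.

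Mice on penicillin carried far more Parabacteroides and Bacteroides at 4 to 12 wk, and almost none of the Ligilactobacillus that SPF mice carried. Parabacteroides, a bile-tolerant anaerobe of the order Bacteroidales, made up 11.3% ± 4.55 in LDP and 0.795% ± 0.468 in SPF samples (n = 11 each). The lowest LDP value, 4.38%, lay above the highest SPF value, 1.99%. Bacteroides, a degrader of plant and host polysaccharides, held 17.8% ± 5.65 in LDP and 4.93% ± 4.97 in SPF samples. Ligilactobacillus, a lactic acid bacterium of the rodent gut, held 0.0173% ± 0.00803 in LDP and 5.33% ± 2.80 in SPF samples. Its highest LDP value was 0.0333% and its lowest SPF value 1.69%. Roseburia, which ferments fiber to butyrate, held 0.143% ± 0.108 in LDP and 1.03% ± 0.516 in SPF samples.

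Genera were compared by limma on log2 of the fraction plus 1e-05, with ages weighted equally and p-values adjusted by the Benjamini-Hochberg method. Folds on this scale understate the change of scarce taxa. The log2 difference of LDP from SPF samples was 3.84 ± 0.31 (SE, adjusted p = 2.62e-09) for Parabacteroides and 2.08 ± 0.40 (adjusted p = 8.21e-05) for Bacteroides. Duncaniella, a mouse-gut member of Muribaculaceae, rose by 1.40 to 7.66% ± 3.33 from 2.81% ± 0.752 (adjusted p = 0.00550). Smaller members of Bacteroidales were also higher: Prevotella at 0.682% ± 0.109 against 0.355% ± 0.0804, Segatella at 0.185% ± 0.0280 against 0.0948% ± 0.0200, and Paraprevotella at 0.115% ± 0.0259 against 0.0557% ± 0.0231. Barnesiella held 0.204% in LDP and 0.130% in SPF samples, a log2 difference of 0.67. The coriobacterium Leptogranulimonas held 0.241% ± 0.143 against 0.142% ± 0.0796 (log2 1.08, adjusted p = 0.000277). Escherichia, a facultative anaerobe that commonly expands after antibiotics, held 0.237% ± 0.191 against 0.122% ± 0.0436 (log2 0.69, adjusted p = 0.0151). Parolsenella (log2 0.62), Porphyromonas (0.60) and Sodaliphilus (0.56) completed the 12 largest increases.

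Among the decreases, Ligilactobacillus fell by 8.17 ± 0.86 on the log2 scale (adjusted p = 7.01e-08). Brachyspira, a spirochete that lives at the colonic mucus, fell by 5.50 to 0.00451% ± 0.00158 from 0.379% ± 0.352. Faecalibaculum, a rodent member of Erysipelotrichales, fell by 4.26 to 0.0364% ± 0.0201 from 0.802% ± 0.465 (adjusted p = 2.62e-09). Its relative Allobaculum fell by 3.41 to 0.0224% from 0.319% ± 0.205. Simiaoa and Kineothrix, both of the class Clostridia, held 0.0359% against 0.267% ± 0.123 and 0.0269% against 0.200% ± 0.134. Turicimonas, which belongs to Pseudomonadota, held 0.0187% against 0.504% ± 0.546. Roseburia fell by 3.02 (adjusted p = 6.61e-07), Lactobacillus by 2.71 to 0.0206% from 0.540% ± 1.37 (0.130% without SPF 4 wk replicate 1), and Agathobacter by 2.55 to 0.0318% from 0.170% ± 0.0744. Anaerocolumna held 0.0247% in LDP and 0.143% in SPF samples. Turicibacter fell by 2.76 over 4 to 12 wk (0.141% ± 0.336 against 0.340% ± 0.614, adjusted p = 0.000207). Its LDP mean was 0.0486% without LDP 12 wk replicate 1, and its SPF mean 0.167% without SPF 4 wk replicate 1.

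In all, 297 of 327 genera passed at 4 to 12 wk (limma, Benjamini-Hochberg), 29 higher and 268 lower in LDP samples. The median genus differed by a log2 of -0.85, and by 0.11 after a centred log-ratio, which sets each genus against the mean log of all genera. On that scale 138 genera were higher and 103 lower. The 12 wk samples alone (n = 2 each, a choice made after the data were seen) passed 57 genera, 5 higher and 52 lower, and 289 of the 297 kept their direction. Parabacteroides and Ligilactobacillus passed there, whereas Bacteroides (log2 1.84, adjusted p = 0.156), Duncaniella (0.86, adjusted p = 0.484) and Roseburia (-1.69, adjusted p = 0.160) kept their direction without passing. Turicibacter turned to a log2 of 1.82 at 12 wk (adjusted p = 0.306), and its adjusted p ranged from 3.63e-06 to 0.306 over the alternatives tried. Escherichia did not pass at 8 to 12 wk (adjusted p = 0.486; range 1.84e-05 to 0.543). Sodaliphilus was the least firm, with adjusted p of 1.09e-05 to 0.274 over the alternatives; it did not pass without LDP 10 wk replicate 2 (0.0518) or SPF 10 wk replicate 1 (0.0521). With a pseudocount of 1e-06, Parolsenella had 0.0705 (range 1.16e-06 to 0.278) and Porphyromonas 0.203 (range 4.98e-06 to 0.269).

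At species rank, Parabacteroides distasonis was higher and Ligilactobacillus murinus lower in LDP samples. Parabacteroides distasonis held 10.8% ± 4.50 in LDP and 0.498% ± 0.228 in SPF samples (log2 4.40 ± 0.31, adjusted p = 3.46e-09). Bacteroides uniformis held 4.05% ± 1.58 against 0.431% ± 0.310 (log2 3.34). Of the Bacteroides entries without a species epithet, the 3 largest rises were 3.49, 3.43 and 3.14. Ligilactobacillus murinus fell by 10.78 ± 0.98 on the log2 scale, to 0.00173% ± 0.000810 from 5.21% ± 2.77 (adjusted p = 3.03e-08). Brachyspira murdochii fell by 5.31, Faecalibaculum rodentium by 4.26, Allobaculum mucilyticum by 3.92 and Roseburia intestinalis by 3.33. Lactobacillus taiwanensis fell by 3.34 to 0.000477% from 0.343% ± 0.980 (0.0494% without SPF 4 wk replicate 1). The soil bacterium entry Streptomyces sp. Je 1-4 4N24_ara held 0.179% ± 0.0946 in LDP samples and was listed at 0 in all 11 SPF samples. It was present in all 9 LDP samples of 4 to 10 wk, at 0.162% to 0.273%, and listed at 0 in all 32 other samples, the LDP samples of 12 wk among them. Of 365 species, 329 passed (limma, Benjamini-Hochberg), 99 higher and 230 lower. The centred log-ratio gave 143 higher and 167 lower, and moved the median species from -1.18 to -0.35. The 12 wk samples alone passed 121 species, 52 higher and 69 lower.

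Under penicillin the community moved from Bacillota toward Bacteroidota. Bacteroidota held 68.1% ± 7.67 in LDP and 36.1% ± 9.11 in SPF samples, with 10 of 11 LDP samples above every SPF sample (log2 0.96, adjusted p = 0.0004). Bacillota, the phylum of lactobacilli and clostridia, held 7.43% ± 3.33 against 29.4% ± 8.87 (log2 -2.07, adjusted p = 0.0003). All 11 LDP samples lay below every SPF sample for Bacillota and for Spirochaetota, which held 0.0407% ± 0.0101 against 0.476% ± 0.352. The log2 ratio of Bacillota to Bacteroidota fell by 3.03. Pseudomonadota held 1.06% ± 0.200 against 1.98% ± 0.422 (log2 -0.89, adjusted p = 0.0004). That fall was about the size of the median genus difference, so it does not set this phylum apart. Phyla were not tested after a centred log-ratio. Actinomycetota held 11.3% ± 6.03 in LDP and 14.2% ± 7.09 in SPF samples and did not pass (adjusted p = 0.675). Campylobacterota (3.00% against 3.19%), Deferribacterota (0.767% against 0.739%) and Thermodesulfobacteriota (0.803% against 0.835%, or 0.532% without SPF 4 wk replicate 2) each had an adjusted p of 0.789. Chlamydiota held 0.0903% ± 0.0626 against 0.435% ± 0.771, or 0.208% without SPF 8 wk replicate 3 (adjusted p = 0.0618; range 0.0228 to 0.132 over the alternatives). It passed without LDP 4 wk replicate 1 (adjusted p = 0.0264), LDP 10 wk replicate 2 (0.0443), LDP 12 wk replicate 2 (0.0450), SPF 8 wk replicate 2 (0.0228), SPF 10 wk replicate 2 (0.0334) or SPF 12 wk replicate 2 (0.0494). These tests are two-sided permutations of SPF and LDP samples within age, adjusted over the phyla and the ratio by Benjamini-Hochberg. Phyla were assigned by hand to 118 genera, which cover 82.1% to 99.1% of a sample.

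Sums over groups of genera chosen before the data were examined were also compared. Because 268 of 327 genera were lower on this scale, a lower sum does not by itself locate the shift. The sums were not tested after a centred log-ratio. Of 16 summed groups, 13 passed a two-sided permutation of SPF and LDP samples within age (Benjamini-Hochberg), 2 higher and 11 lower in LDP samples at 4 to 12 wk. The smallest p these permutations can give is 0.0001. Bacteroidales genera outside Muribaculaceae summed to 33.9% ± 10.9 in LDP and 11.4% ± 5.10 in SPF samples, with 9 of 11 LDP samples above every SPF sample. Of its 9 genera, 5 were higher, 2 lower and 2 did not pass; adjusted over the list alone, 5 and 2 passed, and the centred log-ratio gave 7 higher and 1 lower. The lower ones were Alistipes (0.906% ± 0.170 against 3.05% ± 1.15, log2 -1.61) and Odoribacter (0.0431% against 0.121%). Alistipes did not pass after the centred log-ratio (log2 -0.66, adjusted p = 0.0609; range 5.51e-07 to 0.158). Phocaeicola held 2.70% in LDP and 1.82% in SPF samples (adjusted p = 0.0834; range 2.83e-06 to 0.420). Muribaculaceae, fiber degraders that dominate the mouse gut, summed to 33.6% ± 10.0 against 24.2% ± 9.59 (log2 0.55, adjusted p = 0.0201; range 0.00372 to 0.0692, the highest without SPF 6 wk replicate 1). Among 4 Muribaculaceae genera 2 were higher and 2 did not pass, 1 passed adjusted over the list alone, and all 4 were higher by centred log-ratio. Muribaculum held 19.6% ± 10.2 against 15.3% ± 6.71 (adjusted p = 0.320), and Paramuribaculum 6.06% against 5.88%.

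Several groups of Gram-positive fermenters were lower in LDP samples. Lactobacillaceae, which grow on simple sugars in the upper gut, summed to 0.793% ± 1.26 in LDP and 6.71% ± 5.09 in SPF samples (log2 -4.31, 9 of 11 below every SPF sample), and to 0.466% in LDP samples without LDP 4 wk replicate 1. Of 4 Lactobacillaceae genera 3 were lower, also adjusted over the list alone and by centred log-ratio, and Limosilactobacillus did not pass (0.733% ± 1.26 against 0.736% ± 1.99; 0.406% without LDP 4 wk replicate 1 and 0.138% without SPF 4 wk replicate 1). Erysipelotrichales summed to 0.246% ± 0.345 against 1.52% ± 0.457 (log2 -3.25, 10 of 11 below), and to 0.152% in LDP samples without LDP 12 wk replicate 1. Of 5 Erysipelotrichales genera 4 were lower, among them Catenibacterium (log2 -1.40), 4 passed adjusted over the list alone, and Thomasclavelia had a log2 of -0.02; the centred log-ratio gave 1 higher and 4 lower. Segmented filamentous bacteria, which attach to the ileal wall and drive T helper 17 cells, held 0.00120% ± 0.000523 against 0.0371% ± 0.0431, with 11 of 11 LDP samples below every SPF sample. Their genus Candidatus Arthromitus was lower by either scaling. Lachnospiraceae, fiber-fermenting clostridia, summed to 2.06% ± 1.18 against 8.69% ± 3.77 (log2 -2.19, 9 of 11 below). All 15 of their genera were lower, 15 adjusted over the list alone and 13 by centred log-ratio. Blautia held 0.511% ± 0.296 against 2.23% ± 0.997, Enterocloster 0.350% against 1.51%, and Lachnoclostridium 0.389% against 1.20% (centred log-ratio adjusted p = 0.0951).

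Oscillospiraceae and their relatives, slow-growing clostridia of the colon, summed to 1.80% ± 0.703 in LDP and 5.06% ± 1.82 in SPF samples (log2 -1.53). All 12 of these genera were lower, 12 adjusted over the list alone and 8 by centred log-ratio; Acutalibacter held 0.350% against 1.48%, Faecalibacterium 0.210% against 0.628% and Flavonifractor 0.394% against 0.895% (centred log-ratio adjusted p = 0.169). Butyrate producers, which feed the colonic epithelium, summed to 1.16% ± 0.484 against 4.04% ± 1.59 (log2 -1.83, 9 of 11 below). All 11 were lower, 11 adjusted over the list alone and 9 by centred log-ratio, among them Butyrivibrio (log2 -2.50), Anaerostipes (-2.25) and Eubacterium (-2.12). Cocci and Pasteurellaceae of the suckling age summed to 0.488% ± 0.187 against 1.61% ± 0.539 (log2 -1.75). All 7 members were lower, 7 adjusted over the list alone, whereas the centred log-ratio gave 2 higher and 3 lower; Enterococcus held 0.333% against 1.09% and Streptococcus 0.0648% against 0.250%. Eggerthellales and Coriobacteriales, which transform bile acids and plant compounds, summed to 0.494% ± 0.202 against 0.845% ± 0.196 (log2 -0.83, adjusted p = 0.0003). Of 6 members 4 were lower, 4 adjusted over the list alone, with Adlercreutzia at 0.178% against 0.383%; the centred log-ratio gave 2 higher and 1 lower. Sulfate reducers, whose genus Desulfovibrio makes hydrogen sulfide, summed to 0.0705% ± 0.0363 against 0.160% ± 0.0931 (log2 -1.20, adjusted p = 0.0102). Desulfovibrio was lower (log2 -1.24), also adjusted over the list alone, did not pass by centred log-ratio, and had a log2 of 0.24 at 12 wk alone.

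Enterobacterales, facultative anaerobes that tolerate oxygen, did not pass as a sum at 4 to 12 wk (0.471% ± 0.177 in LDP, 0.530% ± 0.121 in SPF samples, adjusted p = 0.158; range 0.0418 to 0.431, the lowest without SPF 4 wk replicate 1). Escherichia was higher and 6 of 8 genera were lower, 1 and 6 adjusted over the list alone, yet the centred log-ratio gave 3 higher and 0 lower. Klebsiella held 0.0635% against 0.114% (log2 -0.82, turning to 0.14 by centred log-ratio). Genera living in mucus summed to 3.82% ± 2.47 against 3.98% ± 1.68 (adjusted p = 0.716). Of 3 mucus genera only Akkermansia passed, at 0.0462% against 0.0586% (log2 -0.34), also adjusted over the list alone, and 2 were higher and 0 lower by centred log-ratio; Helicobacter held 3.00% against 3.19%, and Mucispirillum 0.767% against 0.739%. Bifidobacterium, an early-life fermenter of milk sugars, held 9.10% ± 6.33 against 11.1% ± 7.10 (log2 -0.10, adjusted p = 0.756). It stood at 0.86 by centred log-ratio (adjusted p = 0.0224) and at -0.97 over 8 to 12 wk (0.0222), with adjusted p of 0.0222 to 0.998 over the alternatives. Bacteria without a peptidoglycan wall, which penicillin cannot reach directly, summed to 0.0247% ± 0.00728 against 0.0771% ± 0.0172 (log2 -1.63). All 11 LDP samples lay below every SPF sample for them, with Spiroplasma at a log2 of -1.53. Genera common in reagents and soil summed to 0.608% ± 0.127 in LDP samples, a log2 of -0.74 from SPF samples (permutation). All 9 were lower, 9 adjusted over the list alone, but 7 turned higher by centred log-ratio; Pseudomonas held 0.276% against 0.455%, and its log2 of -0.73 turned to 0.23.

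**Figure D1:**
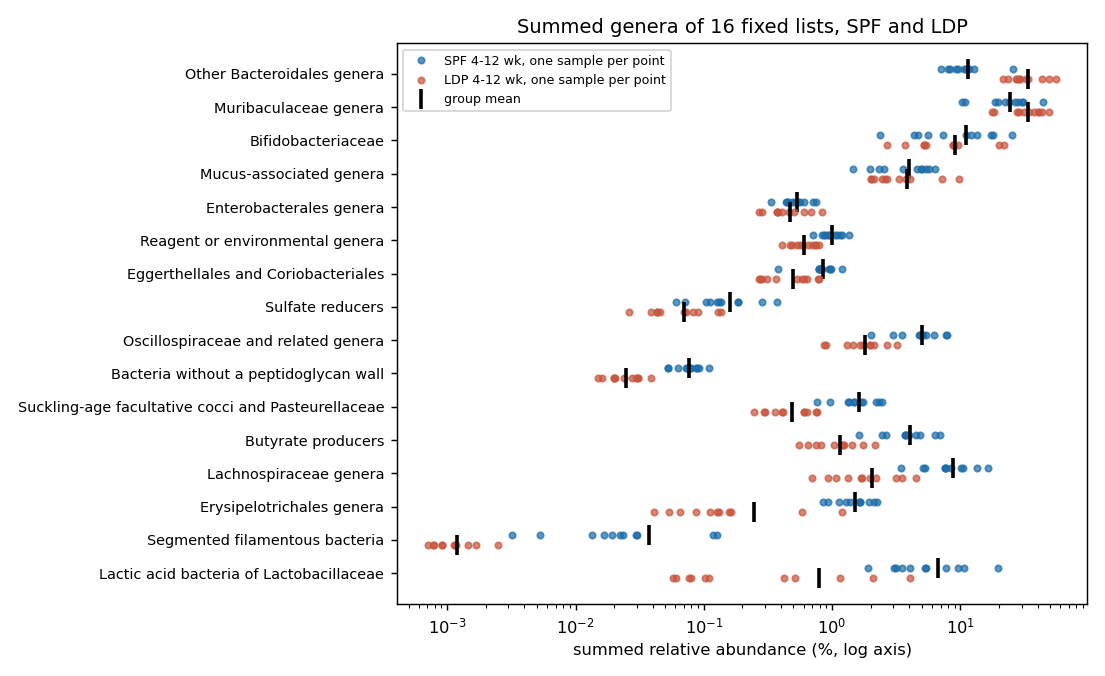
Summed relative abundance (percent of a sample, log axis) of the 16 groups of genera in SPF and LDP samples of 4 to 12 wk; each point is a sample and black bars are group means. Bacteroidales genera outside Muribaculaceae stood at 33.9% in LDP and 11.4% in SPF samples, and Lactobacillaceae at 0.793% and 6.71%; by centred log-ratio the direction of 7 of 9 reagent and soil genera turned.

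Species diversity was lower in LDP than in SPF samples from 4 wk on. The Shannon index, which rises with the number and evenness of species, was 4.21 ± 0.342 in LDP and 5.14 ± 0.470 in SPF samples (n = 11 each). The difference averaged -0.95 over the ages (two-sided permutation within age, p = 0.0001, the smallest the permutations can give). By the same permutation it was -0.62 with only species above a fraction of 1e-04 (p = 0.0002), and -1.03 at genus rank (p = 0.0001). Part of the species difference thus lay in scarce entries. The 10 most abundant genera, led by mean level by Muribaculum, Bacteroides and Parabacteroides in LDP samples, held 79.8% ± 5.03 of a sample there and 57.2% ± 9.25 in SPF samples. LDP against SPF accounted for 49.6% of the Bray-Curtis variance of genera at 4 to 12 wk and age for 17.4% (vegan adonis2 within age, permutation p = 2e-04). At 2 wk the Shannon index was 1.38 ± 0.118 in LDP and 1.41 ± 0.503 in SPF samples (n = 2 each), and Escherichia alone held most of each sample.

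**Figure D2:**
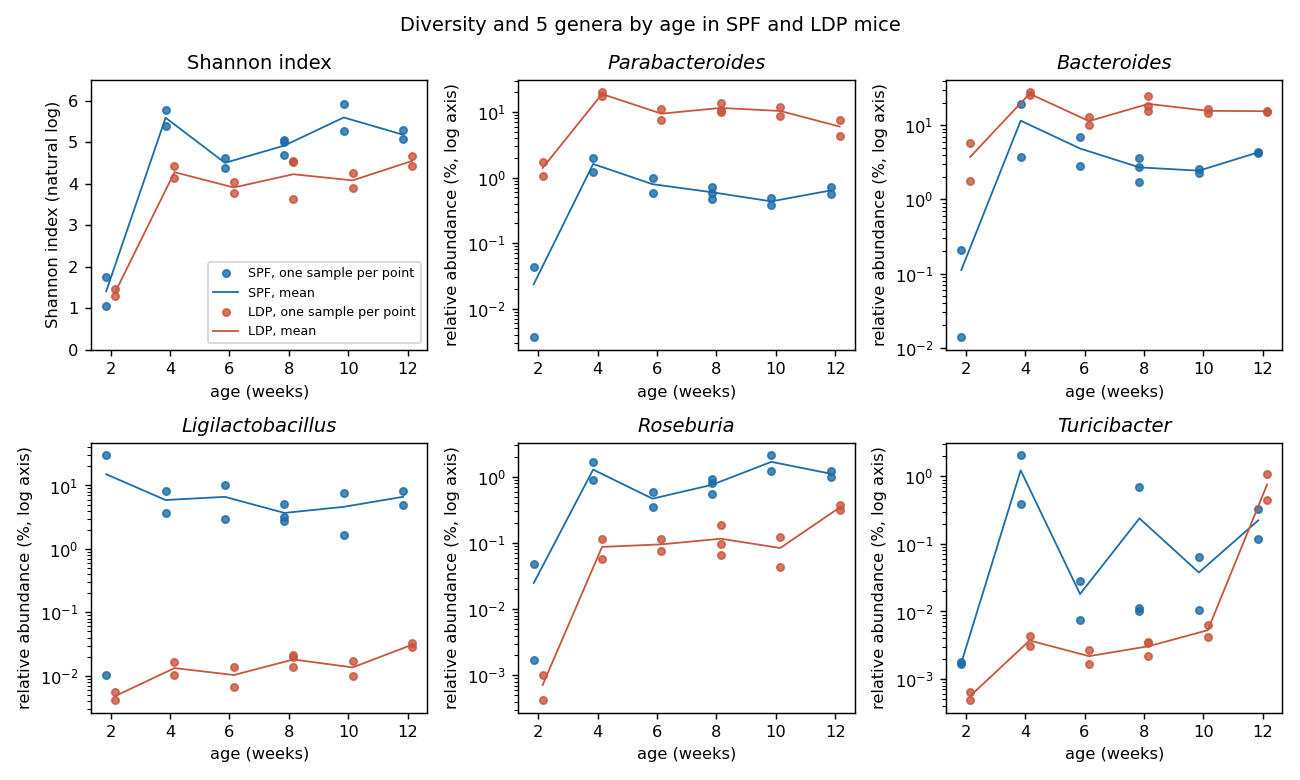
Shannon index of species and levels of Parabacteroides, Bacteroides, Ligilactobacillus, Roseburia and Turicibacter (percent, log axes) against age in weeks for SPF and LDP samples; points are samples and lines are means. Ligilactobacillus stood at 0.0173% in LDP and 5.33% in SPF samples over 4 to 12 wk, while Turicibacter in LDP samples stood at 0.762% at 12 wk and 0.00372% at 4 wk.

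At 2 wk, the usual suckling age, LDP mice already carried Bacteroidales that SPF mice nearly lacked. Phocaeicola held 1.12% ± 0.366 in LDP and 0.00664% ± 0.00767 in SPF samples (n = 2 each; log2 7.67 ± 0.60, adjusted p = 4.12e-08). Parabacteroides held 1.40% ± 0.482 against 0.0236% ± 0.0283 (log2 6.56), and Bacteroides 3.74% ± 2.75 against 0.112% ± 0.139 (log2 5.83). Aggregatibacter, of Pasteurellaceae, held 0.299% ± 0.0280 against 0.0622% ± 0.0192 (log2 2.28), and Enterococcus 8.70% ± 0.799 against 2.25% ± 1.14 (log2 2.05). Staphylococcus, a skin and milk bacterium, fell by 4.41 to 0.0123% from 0.292% ± 0.117. Rodentibacter fell by 1.63 to 1.69% ± 0.167 from 5.35% ± 1.74, and Streptococcus by 1.25 to 2.11% ± 0.194 from 5.03% ± 0.143. Ligilactobacillus held 0.00480% ± 0.000970 in LDP and 15.0% ± 21.2 in SPF samples (log2 -6.67, adjusted p = 0.0302). Escherichia held 76.2% ± 1.17 in LDP and 67.2% ± 24.2 in SPF samples and did not pass. At 2 wk 53 genera passed (limma, Benjamini-Hochberg), 17 higher and 36 lower; the centred log-ratio gave 81 higher and 44 lower, and moved the median from -0.18 to 0.11.

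Within the 2 wk groups, 4 of 9 Bacteroidales genera outside Muribaculaceae were higher in LDP samples, 7 adjusted over the list alone, led by Phocaeicola and Parabacteroides. Of 15 Lachnospiraceae genera 8 were lower, 11 adjusted over the list alone, Blautia and Roseburia among them. Butyrate producers had 5 of 11 lower, 6 adjusted over the list alone, such as Roseburia and Eubacterium. Roseburia held 0.0480% in SPF 2 wk replicate 1 and 0.00170% in replicate 2, against 0.000419% and 0.00101% in the LDP samples. All but the first value lay near the pseudocount, so its difference rests mainly on that 1 SPF sample. None of the 8 Enterobacterales genera passed in limma, also adjusted over the list alone. With the variance taken from the 2 wk samples only, 2 genera passed, Phocaeicola (adjusted p = 0.0344) and Staphylococcus (0.0243). Parabacteroides (0.0781), Bacteroides (0.0923), Aggregatibacter (0.0781) and Rodentibacter (0.0923) did not pass in that fit. Without LDP 2 wk replicate 1 the number was 20, without replicate 2 it was 21, and without SPF 2 wk replicate 2 it was 98. The Ligilactobacillus call ended without LDP 2 wk replicate 1 (adjusted p = 0.156), LDP 2 wk replicate 2 (0.104) or SPF 2 wk replicate 2 (log2 -0.99, 0.412), and its adjusted p ranged from 3.64e-09 to 0.412. Enterococcus did not pass without LDP 2 wk replicate 1 (0.114), replicate 2 (0.0758) or SPF 2 wk replicate 1 (0.122; range 0.000338 to 0.122). Streptococcus did not pass without LDP 2 wk replicate 1 (0.145) or replicate 2 (0.0758; range 0.00146 to 0.145).

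The penicillin effect differed between 2 wk and 4 to 12 wk for 131 genera (limma interaction, Benjamini-Hochberg), 8 with a higher effect at the older ages and the others with a lower effect. By centred log-ratio these were 44 and 53, and the median moved from -0.72 to -0.04. The LDP effect on Phocaeicola changed by a log2 of -7.18 (adjusted p = 4.91e-07) and that on Bacteroides by -3.75 (adjusted p = 0.00802), as the early excess shrank as a ratio. Bacteroides was scarce in the SPF samples of 2 wk (0.0138% and 0.210%). In percent of a sample its mean gap between LDP and SPF samples was larger at 4 to 12 wk than at 2 wk. For Enterococcus the effect changed by -3.78 (adjusted p = 0.000200), from an excess at 2 wk to a deficit later. Aggregatibacter changed by -3.07 and Brachyspira by -5.82, the latter scarce at 2 wk in LDP (0.000903%) and SPF samples (0.000522%). The deficit of Staphylococcus in LDP samples narrowed by 2.92 (adjusted p = 0.00140), and the effect on Leptogranulimonas and Rodentibacter rose by 1.92 and 1.10. Leptogranulimonas did not pass without LDP 2 wk replicate 1 (0.0622), replicate 2 (0.0541) or SPF 2 wk replicate 2 (0.115; range 0.00218 to 0.115). Rodentibacter failed without the same libraries (0.0570, 0.125 and 0.145; range 3.39e-06 to 0.499), Bacteroides without LDP 2 wk replicate 2 (0.0828) or SPF 2 wk replicate 1 (0.0962; range 0.000120 to 0.0962). Without LDP 2 wk replicate 2 the number of genera was 65.

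Between 2 and 4 wk, the usual age of weaning from milk to plant fiber, anaerobes replaced Escherichia in SPF mice. Escherichia held 67.2% ± 24.2 at 2 wk and 0.120% ± 0.0651 at 4 wk (n = 2 each; log2 -9.18 ± 0.59, adjusted p = 1.25e-11). Rodentibacter fell by 10.85 to 0.00185% from 5.35% ± 1.74, Proteus by 4.97 to 0.0126% from 0.425%, and Streptococcus by 4.17 to 0.279% ± 0.0275 from 5.03% ± 0.143. Shigella held 0.570% ± 0.177 at 2 wk and was listed at 0 at 4 wk. Taurinivorans, which respires the taurine of bile acids, and Mucispirillum, a mucus dweller, were listed at 0 at 2 wk and held 2.22% ± 1.81 and 1.43% ± 1.41 at 4 wk. Acutalibacter rose by 9.53 to 2.14% ± 0.407, Oscillibacter by 9.21 to 0.769% ± 0.200 and Dysosmobacter by 8.83 to 0.695% ± 0.248. In SPF samples 318 genera passed (limma, Benjamini-Hochberg), 305 higher and 13 lower at 4 wk. The centred log-ratio gave 118 higher and 91 lower, and the median genus moved from 4.31 to 0.28.

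In LDP mice, too, Escherichia fell between 2 and 4 wk, and Bifidobacterium and Limosilactobacillus had the largest rises. Bifidobacterium rose by a log2 of 11.38 ± 0.69 to 8.78% ± 0.119 from 0.00239% (n = 2 each, adjusted p = 1.45e-11). Limosilactobacillus rose by 10.41 to 3.03% ± 1.38, and Helicobacter, a mucus colonizer, by 10.03 to 2.17% ± 0.405. In SPF samples Bifidobacterium rose to 3.52% ± 1.65 from 0.00823% and Limosilactobacillus to 3.46% ± 4.61 from 0.0138%. The difference in the Limosilactobacillus rise between LDP and SPF samples did not pass (log2 3.91, adjusted p = 0.163). In LDP samples Flavonifractor rose by 8.11 to 0.326% ± 0.190 and Taurinivorans by 8.09 to 0.319% ± 0.0246. Escherichia fell by 7.17 to 0.541% ± 0.176 from 76.2% ± 1.17, with log2 changes of -9.06 for Rodentibacter, -7.08 for Aggregatibacter and -5.96 for Haemophilus. Shigella held 0.754% ± 0.00715 at 2 wk and was listed at 0 at 4 wk. Here 310 genera passed (limma, Benjamini-Hochberg), 291 higher and 19 lower; by centred log-ratio 131 were higher and 102 lower, and the median moved from 3.31 to 0.21. With the variance taken from these samples only, 159 passed.

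At 4 wk the Bacteroidales and clostridial groups stood above their 2 wk levels in SPF and in LDP samples, with Bacteroides and Parabacteroides the larger part in LDP samples. All 9 Bacteroidales genera outside Muribaculaceae rose in either, 9 adjusted over the list alone, and 9 in SPF and 5 in LDP samples by centred log-ratio. In LDP samples Bacteroides held 26.6% ± 1.75 and Parabacteroides 18.8% ± 1.76 at 4 wk; in SPF samples they held 11.5% ± 11.1 and 1.61% ± 0.541. All 4 Muribaculaceae genera rose by either scaling and adjusted over the list alone, and the family summed to 14.5% ± 5.83 in SPF and 18.0% ± 0.503 in LDP samples at 4 wk, against 0.213% and 0.197% at 2 wk. All 15 Lachnospiraceae genera rose in SPF and in LDP samples, 15 adjusted over the list alone; by centred log-ratio 8 rose in SPF, and 11 rose and 1 fell in LDP samples. Lachnospiraceae summed to 10.6% ± 3.99 in SPF and 1.46% ± 0.750 in LDP samples at 4 wk. All 12 Oscillospiraceae and related genera rose in SPF and in LDP samples, 12 adjusted over the list alone, reaching 6.65% ± 1.78 in SPF and 1.30% ± 0.612 in LDP samples; the centred log-ratio gave 10 rises in SPF and 11 rises with 1 fall in LDP samples. All 11 butyrate producers, Roseburia and Faecalibacterium among them, rose in SPF and in LDP samples, 11 adjusted over the list alone, and 8 in SPF and 9 in LDP samples by centred log-ratio. Enterobacterales dropped from 69.1% ± 24.9 to 0.573% in SPF and from 78.4% ± 1.22 to 0.724% in LDP samples. Of 8 Enterobacterales genera 2 rose and 5 fell in SPF samples, 1 rose and 6 fell in LDP samples, with the same numbers adjusted over the list alone, and all 8 fell by centred log-ratio. The suckling-age cocci and Pasteurellaceae went from 13.0% ± 3.15 to 2.31% in SPF and from 12.6% ± 0.780 to 0.683% in LDP samples. Of their 7 genera 1 rose and 4 fell in SPF samples and 2 rose and 5 fell in LDP samples, as adjusted over the list alone; by centred log-ratio 6 and 5 fell and 0 rose.

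The change from 2 to 4 wk itself differed between LDP and SPF samples for 157 genera (limma interaction, Benjamini-Hochberg), 10 higher and 147 lower in LDP samples. By centred log-ratio 34 were higher and 54 lower, and the median moved from -0.96 to -0.02. Turicibacter, a spore-former of the small intestine, gained less under penicillin (log2 -6.79, adjusted p = 0.00886), as did Romboutsia (log2 -5.47, adjusted p = 0.00301). Phocaeicola differed by -6.34 (adjusted p = 7.31e-05), Brachyspira by -5.26 and Bacteroides by -4.18. Leptogranulimonas gained more in LDP samples by 3.94 (adjusted p = 0.00123), Bifidobacterium by 2.88 (0.0235) and Staphylococcus by 3.05; Rodentibacter fell less by 1.79. Bifidobacterium did not pass without LDP 2 wk replicate 1 (0.0746), LDP 4 wk replicate 2 (0.0718) or SPF 4 wk replicate 1 (0.0679; range 0.0122 to 0.0810). Brachyspira did not pass without LDP 4 wk replicate 2 (0.0609) or SPF 4 wk replicate 2 (0.151; range 0.00177 to 0.151), or by centred log-ratio (0.0756). Bacteroides did not pass without LDP 2 wk replicate 2 (0.0832), SPF 2 wk replicate 1 (0.0792) or SPF 4 wk replicate 1 (0.0672; range 0.000688 to 0.154), or by centred log-ratio (0.0939). The number of genera was 86 without LDP 4 wk replicate 2, 82 without SPF 4 wk replicate 2, and 18 with the variance taken from these samples only, where Staphylococcus (0.133) and Rodentibacter (0.232) did not pass.

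Among SPF samples, Leptogranulimonas was higher and Taurinivorans lower at 12 wk than at 4 wk. Leptogranulimonas rose by a log2 of 3.54 ± 0.54 to 0.175% ± 0.114 from 0.0137% ± 0.00830 (n = 2 each, adjusted p = 0.00116). Parolsenella, another coriobacterium, rose by 1.88 to 0.124% (adjusted p = 0.0496). Taurinivorans fell by 3.01 to 0.243% ± 0.134 from 2.22% ± 1.81 (adjusted p = 0.0491), and the skin bacteria Staphylococcus and Corynebacterium fell by 2.11 and 1.81 (adjusted p = 0.0496 each). Of 327 genera 7 passed (limma, Benjamini-Hochberg), 3 higher and 4 lower; the centred log-ratio gave 7 and 4, and the median was -0.05 by either scaling. Without SPF 4 wk replicate 1 the number was 2, without its replicate 2 it was 12, and without SPF 12 wk replicate 1 or 2 it was 2 and 11. Adjusted p over the alternatives ranged from 0.000528 to 1 for Parolsenella, which failed without SPF 4 wk replicate 1 (0.624) or SPF 12 wk replicate 1. It ranged from 1.51e-05 to 0.623 for Taurinivorans, which failed without SPF 4 wk replicate 2 (0.220) or SPF 12 wk replicate 1 (0.623). Staphylococcus and Corynebacterium failed without SPF 4 wk replicate 1 (0.719 each), SPF 12 wk replicate 1 (0.145 and 0.438) or SPF 12 wk replicate 2 (0.262 and 0.141), and ranged from 0.000183 and 0.000124 to 0.719. With a pseudocount of 1e-06 these 4 genera did not pass.

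LDP samples of 12 wk carried more Romboutsia and Turicibacter than those of 4 wk. Romboutsia, a small-intestinal relative of clostridia, held 0.827% ± 0.236 at 12 wk and 0.00294% at 4 wk (n = 2 each; log2 7.69 ± 0.89, adjusted p = 1.32e-05). Turicibacter held 0.762% ± 0.434 against 0.00372% (log2 7.22, adjusted p = 0.00158). Simiaoa rose by 3.05 to 0.117%, Anaerotruncus by 2.88 to 0.115% and Hungatella by 2.28 to 0.156%. Limosilactobacillus fell by 7.30 to 0.0172% from 3.03% ± 1.38 (adjusted p = 0.00557), Staphylococcus by 2.24 to 0.0431% and Escherichia by 1.71 to 0.161% from 0.541% ± 0.176. In LDP samples 152 genera passed (limma, Benjamini-Hochberg), 145 higher and 7 lower at 12 wk. The centred log-ratio gave 26 higher and 39 lower, and moved the median from 0.68 to 0.01. Of 12 Oscillospiraceae and related genera 7 were higher, 8 adjusted over the list alone and 2 by centred log-ratio. Lachnospiraceae had 5 of 15 higher, 5 adjusted over the list alone and 1 by centred log-ratio. Of 11 butyrate producers 5 were higher, 8 adjusted over the list alone and 0 by centred log-ratio. Without LDP 4 wk replicate 2, 13 genera passed, without LDP 12 wk replicate 1, 10, and without LDP 12 wk replicate 2, 51. Hungatella failed without LDP 4 wk replicate 2 (0.197), LDP 12 wk replicate 1 (0.101) or replicate 2 (0.0531; range 0.00622 to 0.197), and Escherichia without the same libraries (0.244, 0.103 and 0.107; range 0.00978 to 0.244). Simiaoa failed without LDP 4 wk replicate 2 (0.0704; range 0.000672 to 0.0704), and Limosilactobacillus and Staphylococcus without LDP 12 wk replicate 1 (0.0520 each; lowest 0.000312 and 0.00208).

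Transfer samples of the 12 to 15 wk window carried more Bacteroidales than those of the 3 to 15 wk window (n = 4 each). Bacteroides held 7.37% ± 4.76 against 1.38% ± 0.498 (log2 2.29 ± 0.50, adjusted p = 0.0141), Phocaeicola 1.47% ± 0.554 against 0.343% ± 0.0526 (log2 2.05) and Parabacteroides 1.13% ± 0.824 against 0.277% ± 0.0823 (log2 1.82). The Parabacteroides mean was 0.731% without GMT 12 to 15 wk replicate 1. Prevotella rose by 1.34 to 0.407% ± 0.134 from 0.158% ± 0.0393 (adjusted p = 0.00892), and Sodaliphilus by 1.62 to 0.158% from 0.0537%. Mucispirillum, which lives in the mucus layer, fell by 4.27 to 0.189% ± 0.184 from 2.20% ± 0.805 (adjusted p = 0.00892), and Turicibacter by 3.33 to 0.0334% ± 0.0420 from 0.296% ± 0.201. Without GMT 12 to 15 wk replicate 4 these means were 0.107% and 0.0125%. Of 501 genera 29 passed (limma, Benjamini-Hochberg), 25 higher and 4 lower; the centred log-ratio gave 27 and 16. Of 9 Bacteroidales genera outside Muribaculaceae 7 were higher, 8 adjusted over the list alone and 7 by centred log-ratio. Muribaculaceae had 1 of 4 higher, 3 adjusted over the list alone, and Erysipelotrichales 2 of 5 lower, 2 adjusted over the list alone, Turicibacter among them. None of 15 Lachnospiraceae or 12 Oscillospiraceae and related genera passed in limma, also adjusted over the list alone. Without GMT 3 to 15 wk replicate 3 or replicate 4 the number was 17 each, without GMT 12 to 15 wk replicate 1 it was 13, and with the variance of these samples only it was 12. Bacteroides failed without GMT 12 to 15 wk replicate 1 (0.0537; range 0.00606 to 0.0537), and Parabacteroides without GMT 3 to 15 wk replicate 3 (0.0603) or replicate 4 (0.0587; range 0.00743 to 0.0808). Sodaliphilus failed without GMT 3 to 15 wk replicates 3 (0.0650) or 4 (0.0866) or GMT 12 to 15 wk replicates 1 (0.110) or 2 (0.0838; range 0.00972 to 0.134). Turicibacter failed without GMT 3 to 15 wk replicates 1 (0.0502) or 4 (0.0790) or GMT 12 to 15 wk replicates 1 (0.0833) or 2 (0.0590; range 0.00457 to 0.0992).

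The other pairs of transfer windows compared did not separate genus by genus. The 12 to 20 wk window was not compared with the 3 to 15 or 8 to 15 wk windows. Between the 8 to 15 and 3 to 15 wk windows limma passed 0 genera (26 at unadjusted p below 0.05). Turicibacter held 0.0246% ± 0.0149 against 0.296% ± 0.201 (log2 -3.26, adjusted p = 0.303) and passed only without GMT 3 to 15 wk replicate 3 (0.0246; range 0.0246 to 0.985), where the number passing was 1. Phocaeicola held 1.22% ± 0.287 against 0.343% ± 0.0526 (log2 1.80, adjusted p = 0.303) and passed only with the variance of these samples (0.00857; range 0.00857 to 0.985). Between the 12 to 15 and 8 to 15 wk windows limma passed 0 genera (29 unadjusted), and 1 without GMT 12 to 15 wk replicate 2. Mucispirillum held 0.189% ± 0.184 against 1.03% ± 0.742 (adjusted p = 0.634; 0.107% without GMT 12 to 15 wk replicate 4), Butyricimonas 0.128% against 0.0809%, and Odoribacter 0.140% against 0.0879%. Between the 12 to 20 and 12 to 15 wk windows (n = 3 and 4) limma passed 0 genera (7 unadjusted). Mucispirillum held 1.36% ± 0.343 against 0.189% ± 0.184 (log2 3.61, adjusted p = 0.598), and Bacteroides 3.41% ± 2.93 against 7.37% ± 4.76 (adjusted p = 0.949; 1.72% without GMT 12 to 20 wk replicate 1).

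Transfer samples ending at 15 wk carried more Brachyspira and Taurinivorans than SPF samples of 8 to 12 wk (n = 12 and 7), and less Alistipes and Chlamydia. Brachyspira held 1.66% ± 0.755 against 0.307% ± 0.223 (log2 2.69 ± 0.52, adjusted p = 0.00130), and Taurinivorans 1.49% ± 0.871 against 0.385% ± 0.361 (log2 1.96), or 0.253% without SPF 10 wk replicate 1. Oscillibacter held 1.05% ± 0.190 against 0.565% ± 0.162, Pusillibacter 0.545% ± 0.0976 against 0.290% ± 0.0833, and Staphylococcus 0.630% ± 0.855 (0.406% without GMT 8 to 15 wk replicate 4) against 0.110% ± 0.0274. Chlamydia, an intracellular parasite, fell by 2.80 to 0.0295% ± 0.0213 from 0.504% ± 0.974, or 0.137% without SPF 8 wk replicate 3. Alistipes fell by 1.62 to 1.06% ± 0.255 from 3.28% ± 0.498, and Leptogranulimonas by 1.44 to 0.0795% from 0.167%. Ligilactobacillus held 1.12% ± 1.52 (0.696% without GMT 3 to 15 wk replicate 3) against 4.79% ± 2.46 (log2 -2.59, adjusted p = 0.0209), and Muribaculum 8.09% ± 4.54 against 16.2% ± 5.16 (log2 -1.12, adjusted p = 0.0382). Of 397 genera 125 passed (limma, Benjamini-Hochberg), 106 higher and 19 lower; the centred log-ratio gave 60 and 37, and moved the median from 0.24 to 0.06. Of 12 Oscillospiraceae and related genera 9 were higher, 10 adjusted over the list alone and 9 by centred log-ratio, summing to 8.59% ± 1.52 against 5.26% ± 1.47. Butyrate producers had 5 of 11 higher, 5 adjusted over the list alone and 5 by centred log-ratio. Muribaculaceae had 2 of 4 lower, 4 adjusted over the list alone and 3 by centred log-ratio. None of 15 Lachnospiraceae genera passed in limma, also adjusted over the list alone (14.1% ± 4.03 against 9.39% ± 3.57 summed).

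Age and window differ between these transfer and SPF samples, so their effects cannot be separated. The number of genera was 78 without SPF 8 wk replicate 3, 46 without SPF 10 wk replicate 2, 78 without SPF 12 wk replicate 2, 263 with the variance of these samples only, and 47 and 204 with pseudocounts of 1e-06 and 1e-04. Staphylococcus failed without SPF 10 wk replicate 2 (0.0836) or SPF 12 wk replicate 2 (0.0755; range 0.0138 to 0.0836). Ligilactobacillus failed without SPF 10 wk replicate 1 (0.0556) or SPF 12 wk replicate 2 (0.0664; range 0.00199 to 0.0664), and Leptogranulimonas without SPF 12 wk replicate 1 (0.0509; range 0.00626 to 0.0509). Muribaculum failed without SPF 8 wk replicates 1 (0.0551) or 3 (0.0603), SPF 10 wk replicate 2 (0.155), SPF 12 wk replicates 1 (0.0757) or 2 (0.0824), GMT 3 to 15 wk replicates 3 (0.0661) or 4 (0.0544), GMT 8 to 15 wk replicate 4 (0.0576) or GMT 12 to 15 wk replicate 3 (0.0662; range 0.0126 to 0.155).

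Against LDP samples of 8 to 12 wk (n = 7), the same transfer samples carried more Brachyspira, Ligilactobacillus and Simiaoa, and less Parabacteroides and Bacteroides. Brachyspira held 1.66% ± 0.755 against 0.00446% ± 0.00109 (log2 8.16 ± 0.52, adjusted p = 5.12e-14), and Ligilactobacillus 1.12% ± 1.52 (0.696% without GMT 3 to 15 wk replicate 3) against 0.0205% ± 0.00814 (log2 5.15). Turicimonas held 0.511% ± 0.489 against 0.0194%, Simiaoa 0.440% ± 0.123 against 0.0471% ± 0.0489, and Lactobacillus 0.993% ± 1.93 (0.460% without GMT 3 to 15 wk replicate 4) against 0.0218%. Parabacteroides fell by 4.18 to 0.620% ± 0.582 from 9.62% ± 3.11 (adjusted p = 1.20e-12), Bacteroides by 2.56 to 3.83% ± 3.69 from 17.2% ± 3.46, and Duncaniella by 2.24 to 1.51% ± 0.898 from 6.52% ± 2.13. Leptogranulimonas fell by 2.36, and Chlamydia by 1.92 to 0.0295% from 0.102%. In this comparison 373 of 397 genera passed (limma, Benjamini-Hochberg), 333 higher and 40 lower; the centred log-ratio gave 152 and 164, and the median moved from 1.04 to -0.06. With LDP samples of 12 wk only, chosen after the data were seen, 346 passed and Chlamydia did not (adjusted p = 0.0577; range 1.66e-05 to 0.0577).

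All 15 Lachnospiraceae genera were higher in the transfer than in the LDP samples by either scaling and adjusted over the list alone, summing to 14.1% ± 4.03 against 2.32% ± 1.39. The same held for all 12 Oscillospiraceae and related genera and all 11 butyrate producers, the latter at 6.76% ± 1.45 against 1.30% ± 0.509. All 4 Muribaculaceae genera were lower by either scaling and adjusted over the list alone (12.8% ± 6.86 against 38.8% ± 6.98). Of 9 other Bacteroidales genera 7 were lower and 1 higher, as adjusted over the list alone, with 0 higher and 8 lower by centred log-ratio, at 7.12% ± 4.77 against 31.1% ± 6.46. Enterobacterales had 6 of 8 genera higher, 6 adjusted over the list alone, but 1 higher and 4 lower by centred log-ratio. All 9 reagent and soil genera were higher, 9 adjusted over the list alone, and 6 turned lower by centred log-ratio.

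As whole communities, all 15 transfer samples lay nearer to SPF than to LDP samples of 8 to 12 wk. Their Bray-Curtis distance was 0.308 ± 0.0646 to SPF and 0.543 ± 0.0968 to LDP samples, and SPF and LDP samples lay 0.431 apart. SPF samples lay 0.193 from each other and LDP samples 0.181. The transfer samples were thus farther from SPF samples than SPF samples were from each other. The distance to SPF minus the distance to LDP samples was -0.278 ± 0.0215 for the 3 to 15 wk window, -0.267 ± 0.0206 for 8 to 15 wk, -0.177 ± 0.0891 for 12 to 15 wk and -0.212 ± 0.0712 for 12 to 20 wk. The 12 to 15 wk window, where Bacteroides was higher, exceeded the 3 to 15 wk window by 0.101 (two-sided exact permutation p = 0.0286, the smallest possible; Benjamini-Hochberg adjusted p = 0.114). Against the 8 to 15 wk window the difference was 0.0902 (exact p = 0.0571, adjusted p = 0.114). Without GMT 12 to 15 wk replicate 1 these differences were 0.0592 and 0.0483. Mean distances to SPF samples were 0.341 (3 to 15 wk), 0.287 (8 to 15 wk) and 0.298 (12 to 15 wk). To LDP samples they were 0.618, 0.554 and 0.475. The 12 to 15 wk window was thus on average nearer to LDP samples than the 3 to 15 wk window, without being farther from SPF samples. The 8 to 15 minus 3 to 15 wk difference was 0.0109 (exact p = 0.514), and the 12 to 20 minus 12 to 15 wk difference -0.0357 (exact p = 0.571). Each had an adjusted p of 0.571, so no pair tested passed. Without GMT 12 to 15 wk replicate 1 the last difference was 0.00622. The 12 to 20 wk window was not compared with the 3 to 15 or 8 to 15 wk windows. The Shannon index of transfer samples was 5.71 ± 0.248, with exact p of 0.629 to 0.886 between the same pairs of windows.

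**Figure D3:**
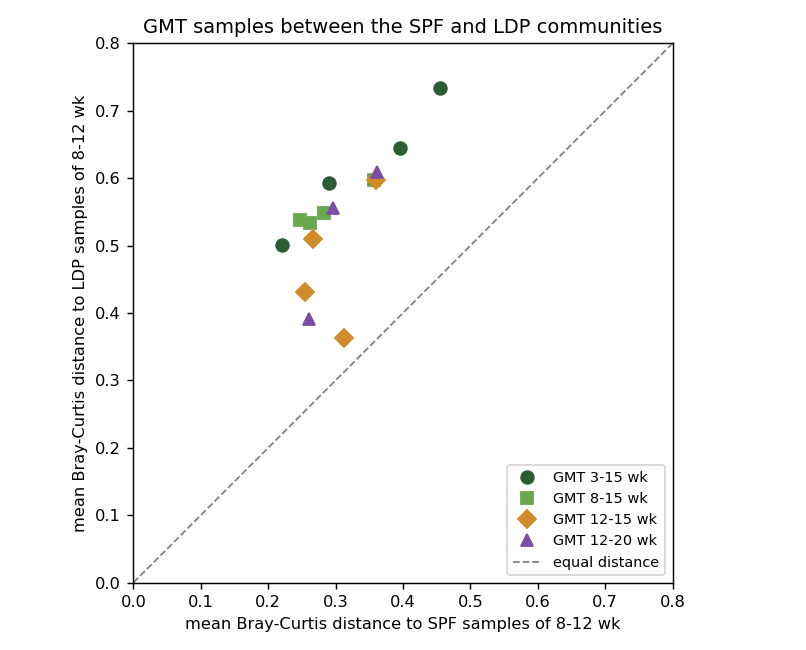
Mean Bray-Curtis distance of each of the 15 transfer samples to SPF samples of 8 to 12 wk (x axis) and to LDP samples of 8 to 12 wk (y axis), with a point per sample coloured by transfer window and a dashed line of equal distance. All 15 points lie above the line, with means of 0.308 to SPF and 0.543 to LDP samples.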

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

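Tests of the wall-less bacteria, of the room beside the genera higher by centred log-ratio, and both tests of the Streptomyces entry were chosen only after the result was seen; the other tests of this part were set before the data were examined.

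Most genera were lower in LDP than in SPF samples at 4 to 12 wk (268 of the 297 that passed). By centred log-ratio, however, 138 were higher and 103 lower. In simulated samples with 200 genera changed, rescaling called 122 of 127 unchanged genera, at a median log2 of -0.82. With no change simulated it called 1. The size of this shift varies with the simulated comparison: that of SPF 4 against 2 wk called 1 of 127 unchanged genera. The 29 genera that rose held 39.6% ± 10.4 in LDP and 10.2% ± 5.39 in SPF samples. Less room beside them would change all others by a log2 of -0.58. Of the 268, 173 lay below this by over 2 SE, which argues against less room beside these 29 as the whole cause. Room beside all 138 would give -1.53, with 38 of the 268 below it by over 2 SE. Part of the 138 are themselves among the 268 and were set against the room left beside themselves. That count therefore decides nothing about them, and less room stays open for the other 230. Reads of Lachnospiraceae and Oscillospiraceae assigned to unrelated genera could explain part. Levels predicted from those families for 241 genera left a median log2 residual of -0.36 ± 0.232 (SD over LDP samples), within 2 SD of 0. Their median observed change was -0.95. That limit measures the spread over samples and not the error of the mean. The prediction was also extended from family levels of 13.7% ± 5.54 in SPF to 3.86% ± 1.84 in LDP samples. Misassigned reads therefore cannot be told apart from a real decrease. Penicillin acting on cell wall synthesis would spare bacteria without a peptidoglycan wall, but their sum was lower than the smaller room gives in 11 of 11 LDP samples, and in 6 with the room beside the 138 genera. Those scarce entries may themselves be misassigned reads, so a direct effect of penicillin stays open, as do indirect effects, which were not tested.

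The entry Streptomyces sp. Je 1-4 4N24_ara stood at 0.218% ± 0.0382 in the 9 LDP samples of 4 to 10 wk and was listed at 0 in 32 others. A batch shared by the LDP samples of 4 to 10 wk is a candidate cause: 8 species were listed in all 9 and in no other sample of 4 wk or older, against at most 1 for any other choice of 9 LDP samples, and 0 of 54 other choices reached as many. The 7 further species held at most 0.00171%, and the split falls between 10 and 12 wk, so an effect of age in LDP mice stays open. A fixed share of the reads of another listed genus is argued against as its source. Of 249 genera only Catalinimonas was higher in all 9 (0.0164% ± 0.00381 against 0.00254% ± 0.000684). A fixed share of it would put the entry at 0.0314% elsewhere, above the smallest value listed (at most 0.000455%). Reads from only a part of a genus need not follow its total and could not be seen by this test, so misassigned reads stay open. No biological explanation was tested.

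Other splits of the same samples were counted for each comparison of at least 3 samples per group. For LDP against SPF genera, 1 of 100 splits, the real one, gave as many as 297 genera, and the highest other gave 267. For species the numbers were 1 of 100, 329 and 292. A chance split of these samples is thus unlikely in either, and 1 is the fewest that 100 splits can give. Splits treat samples as separate, and whether they came from separate animals or cages is not stated. For GMT 12 to 15 wk against 3 to 15 wk, 1 of 35 splits gave as many as 29 genera and the highest other gave 1. A chance split is thus unlikely for this pair of windows taken alone. That is the smallest share 35 splits can give, it is not adjusted over the 4 pairs of windows, and without GMT 12 to 15 wk replicate 1 the number was 13. GMT ending at 15 wk against SPF samples gave 125 genera, reached by 1 of 100 splits with a highest other of 3; against LDP samples it gave 373, reached by 1 of 100 with a highest other of 345. For GMT 8 to 15 wk against 3 to 15 wk and GMT 12 to 15 wk against 8 to 15 wk, limma gave 0 genera (26 and 29 at unadjusted p below 0.05), all 35 splits gave as many, and the highest other was 7. For GMT 12 to 20 wk against 12 to 15 wk limma gave 0 (7 unadjusted), all 35 splits gave as many, and the highest other gave 122, which points to a structure of these samples; what that split separates was not tested.

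Over 26 measures in each of the 3 groups of 4 samples, 5 of 78 tests found a sample apart from the other 3 by more than Dixon's critical ratio; chance alone does this in about 1 of 20 tests, and these tests share their samples. Lactobacillus held 0.687% in GMT 8 to 15 wk replicate 1, against 0.0598% to 0.0643% in the others. Ligilactobacillus held 5.76% in GMT 3 to 15 wk replicate 3, against 0.234% to 0.762%. Staphylococcus held 0.922% in GMT 3 to 15 wk replicate 4 (others 0.141% to 0.195%) and 3.09% in GMT 8 to 15 wk replicate 4 (others 0.104% to 0.128%). Turicibacter held 0.0962% in GMT 12 to 15 wk replicate 4, against 0.00873% to 0.0179%.

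The LDP effect at 4 to 12 wk differed from that at 2 wk for 131 genera in a limma interaction test. The log2 differences were 2.92 for Staphylococcus, 1.92 for Leptogranulimonas, 1.10 for Rodentibacter, -7.18 for Phocaeicola, -5.82 for Brachyspira, -3.78 for Enterococcus, -3.75 for Bacteroides and -3.07 for Aggregatibacter. The change from 2 to 4 wk differed between LDP and SPF samples for 157 genera in the same kind of test. Those log2 differences were 3.94 for Leptogranulimonas, 3.05 for Staphylococcus, 2.88 for Bifidobacterium, 1.79 for Rodentibacter, -6.79 for Turicibacter, -6.34 for Phocaeicola, -5.47 for Romboutsia, -5.26 for Brachyspira and -4.18 for Bacteroides.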

How the results depend on the processing

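Tests with 12 wk samples only, or without 12 wk samples, were chosen only after the result was seen; all other alternatives were set before the data were examined. Family rank and a replicate block for GMT against SPF or LDP samples were not run.

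A looser filter lets more taxa be tested. A filter of 1e-05 and no filter gave 1425 and 1997 genera for LDP against SPF at 4 to 12 wk, 3549 and 7799 species, 98 and 88 genera at 2 wk, and 809 and 1090 for the LDP effect at 4 to 12 wk minus 2 wk. They gave 1568 and 2122 for SPF 4 against 2 wk, 1483 and 1836 for LDP, 869 and 1122 for the difference of those changes, 19 and 29 for SPF 12 against 4 wk, and 634 and 738 for LDP. GMT 12 to 15 against 3 to 15 wk had 57 and 61, GMT against SPF 552 and 661, and GMT against LDP 1620 and 2031.

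A pseudocount of 1e-06 gave 143 genera at 2 wk, 92 for the difference of the weaning changes, 2 for SPF 12 against 4 wk, 32 for LDP 12 against 4 wk and 47 for GMT against SPF. With 1e-04 these were 11 at 2 wk, 206 for the LDP effect minus that at 2 wk, 14 for SPF 12 against 4 wk and 204 for GMT against SPF. The centred log-ratio gave 125 at 2 wk, 209 for SPF 4 against 2 wk, 88 for the difference of the weaning changes, and 11 and 65 for SPF and LDP 12 against 4 wk. Spread from only the groups compared gave 2 at 2 wk, 159 for LDP 4 against 2 wk, 18 for the difference of the weaning changes, 19 for SPF 12 against 4 wk, 1 and 12 for GMT 8 to 15 and 12 to 15 against 3 to 15 wk, and 263 for GMT against SPF. Without a trend SPF 12 against 4 wk gave 4. The 12 wk samples alone gave 57 genera and 121 species for LDP against SPF.

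Replicate numbers as a fixed block gave 25 genera at 2 wk and 3 for SPF 12 against 4 wk; as a random block (consensus correlation -0.058) they gave 2 for SPF 12 against 4 wk. With the fixed block the Shannon difference was -0.93 (permutation p = 0.001). Of the values of named taxa, 157 of 164 kept their call with the fixed block and 143 of 148 with the random block.

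Directions turned for 15 of 2271 values of named taxa. With the 12 wk samples alone, log2 was 1.82 for Turicibacter, 0.33 for Anaerotruncus and 0.24 for Desulfovibrio; the cause was not tested. The centred log-ratio, which by construction adds a near-constant amount to all genera, turned Shigella (0.96), Klebsiella (0.14), Citrobacter (0.031), Salmonella (0.35), Rodentibacter (0.43), Mucispirillum (0.68), Bifidobacterium (0.86), Collinsella (0.91), Bradyrhizobium (0.21), Pseudomonas (0.23), Burkholderia (0.28) and Sphingomonas (0.26). Of the rest, 2103 kept their direction and call, 131 no longer passed (57 of them with the 12 wk samples alone) and 22 newly passed. Of 176 comparison results, 125 stayed within 1.5 times.

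Leaving out each sample in turn gave 289 to 304 genera and 315 to 331 species for LDP against SPF, 20 to 98 at 2 wk, and 65 to 147 for the LDP effect minus that at 2 wk. SPF 4 against 2 wk gave 311 to 331, LDP 303 to 315, the difference of these 82 to 184, SPF 12 against 4 wk 2 to 12, and LDP 10 to 159. GMT 8 to 15 against 3 to 15 wk gave 0 to 1, 12 to 15 against 3 to 15 wk 13 to 35, 12 to 15 against 8 to 15 wk 0 to 1, 12 to 20 against 12 to 15 wk 0, GMT against SPF 46 to 154, and against LDP 366 to 382. The Shannon difference was -1.01 to -0.88, lists past the threshold 12 to 14, phyla and ratio 5 to 6, and LDP against SPF held 46.1% to 52.5% of the Bray-Curtis variance. Of the distance differences, no pair passed, which so few samples could hardly do after adjustment. These differences were 0.00215 to 0.0203 (8 to 15 minus 3 to 15 wk) and 0.0592 to 0.123 (12 to 15 minus 3 to 15 wk). The others were 0.0483 to 0.112 (12 to 15 minus 8 to 15 wk) and -0.0767 to 0.00622 (12 to 20 minus 12 to 15 wk). Of 3483 values of named taxa, 3398 kept their direction and call, 71 no longer passed and 14 newly passed.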

Other observations

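The LDP samples of 12 wk held Romboutsia at 0.827% ± 0.236 and Turicibacter at 0.762% ± 0.434, above the levels of 4 wk. The Streptomyces entry, present in the 9 LDP samples of 4 to 10 wk, was listed at 0 in them. No test set the 12 wk against the 6 to 10 wk LDP samples. Age and a change of batch cannot be separated here, because no SPF or GMT sample carries that entry.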
